A study of Mus musculus with 12 samples.

How the data were processed

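The study measured RNA from whole ovaries of mouse embryos at day 16.5 (E16.5), from Fmr1 knockout (KO) and wild-type (WT) animals. Each sample held 5 pairs of ovaries, per the labels' protocols. The 12 libraries were 3 KO and 3 WT input libraries, made from part of the homogenate, and 3 KO and 3 WT libraries of RNA immunoprecipitated with an antibody against FMRP, the RNA-binding protein that Fmr1 encodes. The last kind is RNA immunoprecipitation followed by sequencing (RIP). The labels call the samples biological replicates. The design text calls the WT input animals littermates, without saying which pools shared litters.

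The input files hold read counts per gene, deposited without normalization. Per the file headers, the counts were made with featureCounts 1.6.3 over exons, summed by gene identifier, with the Ensembl release 104 annotation. The command carried no option for strand, for read pairs or for reads with several placements. Reads of overlapping and antisense genes cannot be told apart in such counts, and genes with near-identical copies, among them those shared by the distal ends of X and Y, are uncertain. The submitters' processing notes list FastQC, BWA 0.7.12, MACS2 2.1.0, DESeq2 1.26.0 and the build GRCm38, with no role for any of them. BWA does not split reads over introns, so if it placed these reads, those across exon junctions were partly lost, more so in genes with short exons. The coordinates given here are those of the count files. Their annotation release belongs to a later build than the one in the notes, and no coordinate was converted.

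The RIP table holds fold enrichments, a linear ratio computed by the authors, deposited as 1 column for each of the 6 RIP libraries. What the ratio is relative to, how rows were chosen and where each row lies on its transcript are not given in the sources used here. The table had 14447 rows for 7525 gene identifiers. A gene could have several rows (3174 genes did, up to 54 each), and 1536 rows repeated all 6 values of another row. Each row exceeded 1 in at least 1 library, the lowest maximum being 1.01, and no row belonged to the Y chromosome or the mitochondrial genome. The rows lay in the order of the p-value from an unequal-variance comparison of the KO and WT ratios, over all 14446 steps. A further table of peak comparisons that the labels mention was not analysed here. No read depth stands behind the ratios in the files used, so their counting error is unknown.

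Input counts were tested with edgeR 4.0.16 (R 4.3.3), using TMM normalization, filterByExpr, robust dispersions and the quasi-likelihood test, KO over WT, with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes are the estimate divided by the square root of the F statistic. Levels are CPM, counts scaled to library size with TMM factors, also for sums over chromosome ends. RIP ratios are not counts, so they were tested with limma 3.58.1 (eBayes with a trend) on log2(value + 1), each column centred on its median, over rows with a mean of at least 1, WT over KO. On this scale the log2 difference understates the change of low values; folds given for RIP rows are ratios of group means of the deposited values. For tests per gene, the row with the highest mean was taken. Gene sets were tested with camera (preset correlation of 0.01), with an estimated correlation and with fry. Single values were compared with two-sided exact permutation tests, for which 3 against 3 libraries allow no p below 0.1.

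Input totals ran from 18880238 to 25707718 counted reads per library. Replicates differed from each other by more than sampling noise in all pairs (chi-square per degree of freedom of 8.12 to 14.2), so none was counted as a repeat of another. The biological coefficient of variation was 12.1%. The edgeR step was run on 23698 simulated genes with the real input means and library sizes, with 12 false calls. The changed genes were drawn from those with a mean CPM above 1, so recovery below that level was not measured. It recovered 30 of 50 genes changed 1.5-fold, 36 of 50 changed 2-fold, 47 of 50 changed 3-fold and 48 of 50 changed 4-fold. On simulated RIP values the limma step, run on 14365 rows, recovered 22, 36, 39 and 46 of 50 rows at these 4 settings, with 8 false calls. There the folds were of value + 1, so they stand for larger folds of the ratio itself. Recovery at a given fold of the ratio was therefore lower than these counts. In both simulations the 4 settings were changed in the same run and adjusted together. The adjustment is less strict when more features change, so recovery with few true changes can be lower and was not measured.

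The files do not pair gene identifiers with names. The RefSeq gene table used for names (assembly GRCm38.p6) held 0 of the identifiers. All 37 mitochondrial genes had the same start and end in both sources and took their names from that table. Fmr1 was taken as ENSMUSG00000000838, its Ensembl identifier and the gene the study targeted. It was the only X gene whose span (39423 bp) lay within 50 bp of the span of Fmr1 in RefSeq (39428 bp). Other genes are given by identifier or position. Of 27 gene lists fixed before the data were examined, 1 could therefore be tested, the mitochondrially encoded mRNAs. The other 26, which covered germ cell, meiotic, somatic and FMRP target genes, were not scored.

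The tests, samples and alternatives were also fixed before the data were examined. The genes to name were Fmr1, then up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold with a mean CPM of at least 1 and groups that did not overlap. In RIP they were Fmr1 and its paralogs, then the largest ratios among rows past the threshold, or the 10 rows with the smallest p where fewer than 5 passed. The rule's further condition, a proper gene symbol, could not be applied, nor could the paralogs be found. Alternatives were DESeq2 1.42.0, limma-voom, other size factors, other filters, pseudocounts and scalings, the replicate number as a block, and leaving out each library. Count tools were not run on the RIP ratios. A surrogate variable (sva 3.50.0), robust moderation, rows averaged per gene, identical rows counted once, an unequal-variance test per row, and the sets defined by chromosome, gene length or rows per gene were chosen after seeing the data. The alternatives run on the Fmr1 RIP row alone were also chosen after seeing the data. The correlation of length with the RIP difference was among the tests fixed earlier.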

Results

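RNA was measured in whole E16.5 mouse ovaries of 2 genotypes, Fmr1 KO and WT, in 3 input and 3 anti-FMRP RIP libraries per genotype. The input libraries held 18880238 to 25707718 counted reads over 55416 annotated genes. The gene with the highest count took 8.03% to 9.75% of a library, and mitochondrial genes took 2.51% to 2.85%. P-values measure the spread between these pools of 5 ovary pairs.

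The first question was whether the targeted gene differed between the groups. Fmr1 (ENSMUSG00000000838, X chromosome, 67722147 to 67761569, exonic length 8966 bp) encodes FMRP, an RNA-binding protein that regulates translation. Its transcript stood at 101 ± 19.8 CPM in KO input (SD, n = 3) and 213 ± 8.47 CPM in WT input (SD, n = 3), so that it fell in KO to 47.4% of the WT level. The log2 change was -1.08 (SE 0.11, adjusted p = 0.00775, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The read counts were 1644, 2968 and 1763 in the KO libraries and 5177, 4880 and 4664 in the WT libraries. Counts per gene do not show which exons the remaining reads came from, and the labels do not state whether the KO ovaries were homozygous.

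In the RIP table, Fmr1 had 1 row, with a fold enrichment of 0.422 ± 0.029 in KO (SD, n = 3) and 1.39 ± 0.045 in WT (SD, n = 3). WT lay 3.30-fold above KO, and the groups did not overlap (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). This was the lowest KO mean of all rows. Fmr1 is also the gene altered in KO, and its input RNA fell there to 47.4% of the WT level. What the ratio is relative to is not given, so the row does not show whether FMRP bound this transcript. The row's mean of 0.906 lay under the filter of 1, so the main test left it out. Without the filter it was the only row past the threshold (log2 difference 0.75, SE 0.054, adjusted p = 0.0216, limma). That call ended with any 1 of the 6 libraries left out, with quantile normalization (adjusted p = 0.0683) and with 1 surrogate variable (adjusted p = 0.106), with differences of 0.71 to 0.77. It held with no centring (adjusted p = 0.0333) and with pseudocounts of 0.1 and 10 (adjusted p = 0.0388 and 0.0105), which set the log2 difference at 1.52 and 0.13.

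**Figure D1:**
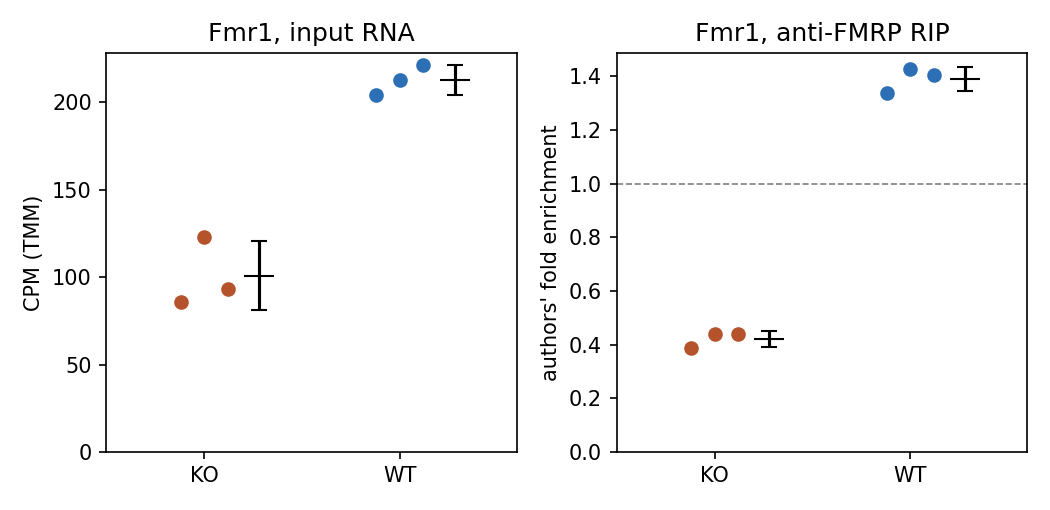
Fmr1 in each library: input level in CPM (left) and the authors' fold enrichment after RIP (right, dashed line at 1) for KO and WT, with 1 point per library and the mean ± SD of 3 beside them. Every KO library lies below every WT library on both axes.

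The second comparison asked which transcripts differed in abundance in the KO ovary. Of 23698 tested genes, 10 passed as lower in KO and 0 as higher (edgeR, Benjamini-Hochberg adjusted p under 0.05). Genes that did not pass are not shown to be unchanged, since changed genes were also missed in the simulation. Of the 10, 6 lay on the X chromosome, 2 on chromosome 7, and the others on chromosomes 14 and 18. The 6 X genes were Fmr1, 1 other, and 4 neighbours that overlap or lie beside each other. The tested X genes as a set did not stand apart from other genes (camera adjusted p = 0.995). Apart from Fmr1, the estimated folds ran from 1.74 to 10.9.

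A cluster at the distal end of the X chromosome held 4 of the 10 genes, within 334 kb (168468195 to 168802277). The largest fall of all was ENSMUSG00000087263 (X, 168762043 to 168768228), at 0.201 CPM in KO and 2.17 CPM in WT (log2 change -3.44, SE 0.58, adjusted p = 0.0361). It lost its call with KO replicate 2 or any WT replicate left out, and its log2 change was -5.39 without KO replicate 1. The most abundant of the cluster, at 168792655 to 168802277, stood at 17.8 CPM in KO and 60.0 CPM in WT (log2 change -1.75, SE 0.19, adjusted p = 0.0287). The longest, spanning 168468195 to 168788732, stood at 12.04 and 27.8 CPM (log2 change -1.21, SE 0.18, adjusted p = 0.0152). The remaining member, at 168758039 to 168761913, had a log2 change of -3.08 (SE 0.39, adjusted p = 0.00425). A gene 0.3 Mb further out, at 169106356 to 169111844, had 11.96 CPM in KO and 10.8 in WT and did not pass (adjusted p = 0.976). Summed over the 10 annotated genes from 168468195 to the end of the X annotation, input reads, scaled to CPM, were 43.5 ± 10.2 in KO and 106 ± 6.79 in WT (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). The region starts at a called gene, so this sum is not independent of the calls. Overlapping genes and copies shared with Y make the share of each single gene uncertain.

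The distal end of the Y annotation, 5 genes from 90763696 to 90855309, also had fewer reads in KO, at 28.1 ± 8.90 CPM in KO and 114 ± 5.85 in WT (SD, n = 3 each; exact permutation p = 0.1). The 2 ends together had 71.6 ± 18.6 CPM in KO and 220 ± 5.67 in WT, a 3.07-fold difference. They share near-identical sequence, so reads counted at Y can come from X, and the 2 falls are not separate observations. None of the 4 tested Y genes of that end passed (edgeR), with 3 at an unadjusted p under 0.05. The most abundant of them, at 90796007 to 90827734, stood at 24.4 CPM in KO and 103 CPM in WT (adjusted p = 0.0887).

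**Figure D2:**
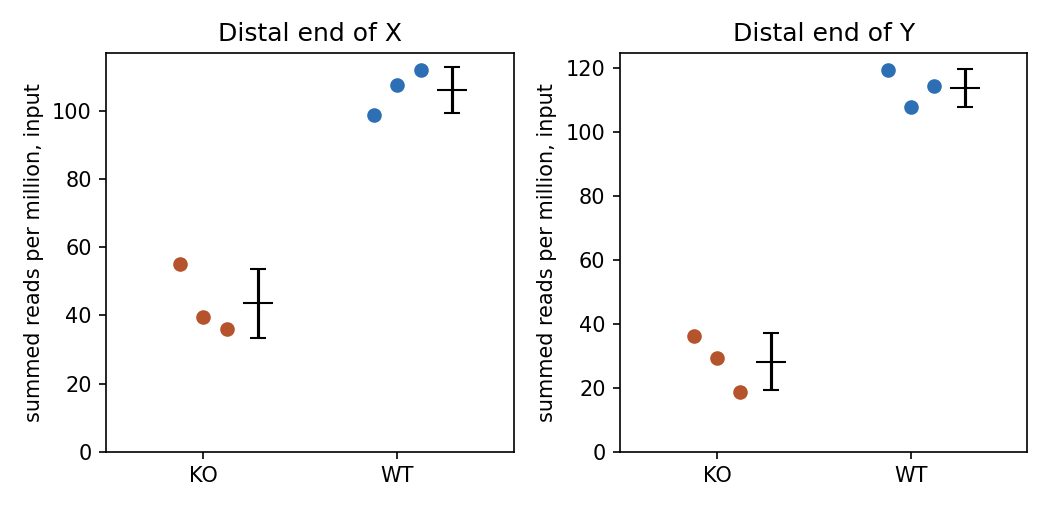
Input reads at the distal ends of X and Y in each KO and WT library, scaled to CPM, with 1 point per library and the mean ± SD of 3. Every KO library lies below every WT library at both ends.

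Outside that cluster, the largest fall was ENSMUSG00000117490 (chromosome 18, 8180579 to 8192719), at 0.202 CPM in KO and 1.83 CPM in WT (log2 change -3.11, SE 0.48, adjusted p = 0.00775). A further X gene, at 142936691 to 142949270, stood at 2.21 and 6.77 CPM (log2 change -1.62, adjusted p = 0.00440). The chromosome 7 genes, at 29626403 to 29629830 and 94018190 to 94021779, had log2 changes of -1.61 and -1.28. The chromosome 14 gene, at 56178908 to 56182132, stood at 18.2 and 31.7 CPM (log2 change -0.80, SE 0.11, adjusted p = 0.00440).

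**Figure D3:**
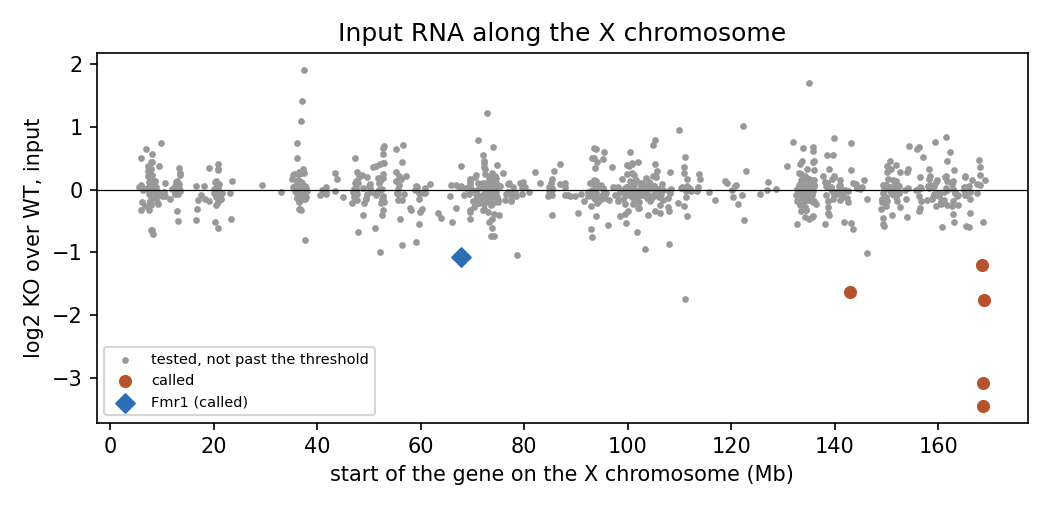
Input log2 fold change (KO over WT) of each tested X gene against its start in Mb, with called genes in colour and Fmr1 as a diamond. Of the 915 tested X genes, 6 were called, and 4 of them lie between 168468195 and 168802277.

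The number of called genes moved with the setting. At an unadjusted p under 0.05, 1399 genes differed (688 higher and 711 lower in KO), where 1185 would be reached by chance. With no low-count filter 113 genes were called, 48 of them higher in KO. DESeq2 called 37 genes, 17 of them higher in KO and 9 shared with the 10 above. Leaving out KO replicate 1, KO replicate 2 or WT replicate 2 gave 37, 5 and 28 genes. Without KO replicate 1, 19 of the 37 were higher in KO.

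Of 153 tested genes within 10 Mb of Fmr1, Fmr1 itself was called and 0 others were (edgeR), with 12 others at an unadjusted p under 0.05. The 13 mitochondrially encoded mRNAs, which encode subunits of the respiratory chain and ATP synthase, took 2.17% ± 0.19 of KO reads and 2.15% ± 0.10 of WT reads (SD, n = 3 each). None passed the test, over all genes or adjusted over the list alone. COX1, a subunit of cytochrome oxidase, stood at 7040 ± 281 CPM in KO and 7232 ± 328 in WT. CYTB, of the cytochrome bc complex, stood at 2400 ± 229 and 2418 ± 141 CPM, and ND4L had the highest estimate of the list (log2 change 0.11, SE 0.098, adjusted p = 0.972). The list as a set did not stand apart from other genes (camera p = 0.958; p = 0.988 with an estimated correlation), and a common direction of its genes was not detected (fry p = 0.982).

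The third comparison asked which transcripts the antibody enriched in WT ovary over the KO background. None of the 14365 tested rows passed (limma, smallest adjusted p = 0.375), so that 0 rows were both past the threshold and above 1.5-fold. At an unadjusted p under 0.05 there were 859 rows higher in WT and 413 higher in KO, against 718 by chance in both directions together. Without WT replicate 1 these were 796 and 622. Rows are not independent, so the number reached by chance varies more than if they were. Splits of the libraries other than by genotype gave from 472 to 1248 rows in both directions together. The unequal-variance test of the deposited ratios also gave 0 rows after adjustment, with 485 higher in WT and 356 higher in KO before it. Among the 10 rows with the smallest p, none past the threshold, 8 were higher in WT, by 1.79-fold to 3.05-fold, and the other 2 were 1 set of values listed for 2 overlapping genes.

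Of these 10, ENSMUSG00000010277 (chromosome 11, 78152578 to 78181449) had a fold enrichment of 1.23 ± 0.14 in KO and 2.59 ± 0.23 in WT (adjusted p = 0.375, limma). ENSMUSG00000026490 (chromosome 1, 179788037 to 179993168) had 0.928 ± 0.078 in KO and 1.66 ± 0.018 in WT. The highest ratio, 3.05, was that of a chromosome 3 gene at 125658920 to 125732268, with 0.956 ± 0.24 in KO and 2.92 ± 0.80 in WT. Rows of genes on chromosomes 6 (82923883 to 83007290), 9 (95739650 to 95833834), 11 (102554542 to 102573063), 16 (13489722 to 13521476) and 19 (4336029 to 4356250) had ratios of 2.02, 2.09, 2.47, 1.96 and 1.98. The chromosome 19 gene had a second row that was higher in KO at an unadjusted p under 0.05, so it had no single direction. In the other direction, ENSMUSG00000108878 and ENSMUSG00000038503 (chromosome 7, 83541470 to 83545605 within 83533674 to 83550740) shared a row with 2.56 ± 0.20 in KO and 1.18 ± 0.11 in WT. All SDs are over 3 libraries. All 10 rows had groups that did not overlap, but they were chosen for a small p, so this adds no support. Of rows not chosen in this way, 10% would lack overlap by chance.

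Genes were also ranked by exonic length, with 1 row per gene. Of the longest 1870 genes (6490 bp or more), 140 were higher in WT and 46 higher in KO at an unadjusted p under 0.05, against 282 and 185 of the other 5608. As a set the longest genes did not pass (camera p = 0.0234, adjusted p = 0.164 over 7 sets; adjusted p = 0.132 with an estimated correlation). With WT replicate 1 left out the counts were 133 and 99, against 270 and 371 of the other genes, so that over all genes more were higher in KO. The counts of long genes were 135 and 27 without WT replicate 2 and 119 and 30 without KO replicate 3. On the X chromosome, 18 of 249 genes were higher in WT and 3 higher in KO (camera adjusted p = 0.369). Those counts were 14 and 5 without KO replicate 1, 22 and 5 without KO replicate 3, and 15 and 6 without WT replicate 1. Across 7478 genes, length and the WT over KO difference had a Spearman correlation of 0.0905, with 0.0174, 0.144 and 0.00177 for replicate numbers 1, 2 and 3; genes are not independent replicates.

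**Figure D4:**
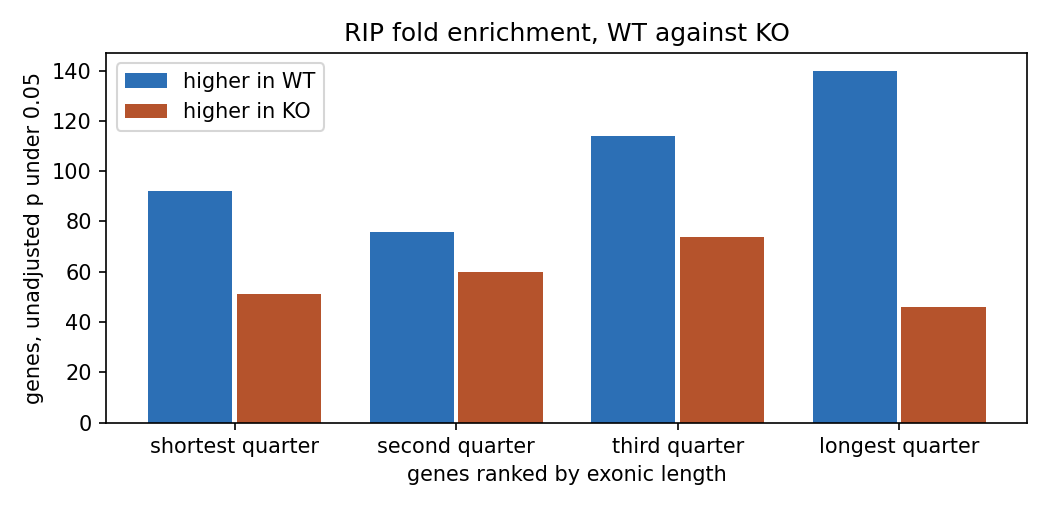
Number of genes with a RIP fold enrichment higher in WT or higher in KO at an unadjusted p under 0.05, for genes ranked by exonic length in 4 groups of equal size. The longest genes had 140 higher in WT and 46 higher in KO, and no gene passed after adjustment.

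The RIP libraries differed from each other in ways that the genotype did not follow. The 99th percentile of the fold enrichments was 10.4, 25.1 and 17.1 in KO replicates 1 to 3 and 21.7, 10.3 and 11.6 in WT replicates 1 to 3. Column medians lay close together, from 1.72 to 1.78. The first principal component held 48.8% of the variance, with scores of -25.0, 31.9 and 13.3 for KO and 29.1, -24.7 and -24.7 for WT.

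The last comparison asked whether transcripts with higher RIP ratios in WT differed in abundance in KO input. The 100 rows with the highest moderated t stood for 82 genes tested in the input, of which 46 had a positive and 36 a negative estimate and 0 were called (edgeR), with 10 higher and 1 lower at an unadjusted p under 0.05. Their mean log2 change was 0.046 (median 0.016; camera p = 0.0837; p = 0.525 with an estimated correlation). It was 0.012 without KO replicate 2 or WT replicate 1 and 0.070 without KO replicate 3 or WT replicate 3. The set passed without KO replicate 1, KO replicate 3 or WT replicate 3 (camera with the preset correlation, p = 0.0369, 0.0323 and 0.0378). Across 6965 genes the RIP difference (WT over KO) and the input difference (KO over WT) had a Pearson correlation of 0.117 and a Spearman correlation of 0.178. Simulated libraries with no change between groups, in which each ratio had its own input as denominator, gave a Pearson correlation of 0.246 (100 draws). The observed covariance was 0.00542 and the simulated one 0.0115. With the RIP values of 1 replicate number and the input of the other 2 numbers, the Pearson correlations were -0.0800, -3.82e-05 and -0.0200, and the mean input changes of the 100 genes with the highest RIP difference of that number, a new set each time, were -0.066, -0.020 and -0.064 (camera p = 0.00472, 0.920 and 0.0344). With RIP and input of the same number, the Pearson correlations were 0.121, 0.132 and 0.160 for numbers 1, 2 and 3. A positive relation was therefore seen only where libraries of the same number were compared. Each crossed value rests on 1 RIP library per group, so differences between RIP libraries may also enter it.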

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

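The surrogate variable, the averaged rows and the fits without the chromosome ends were chosen after seeing the data. The fall of Fmr1 in KO input held its direction and its side of the threshold in all 12 alternatives given for it, with log2 changes from -1.25 to -0.97. The limma-voom fit was not among them. The count of 10 input genes was 113 with no low-count filter (48 higher in KO), 37 with DESeq2 (17 higher in KO), 6 without the distal ends of X and Y, which hold 4 of them, and 6 with 1 surrogate variable, of which 5 were among the 10. Leaving out a library gave 37 genes (KO replicate 1), 28 (WT replicate 2), 5 (KO replicate 2) and 7 to 11 otherwise; the cause was not tested. With the replicate block there were 19 genes, 4 of them higher in KO and 8 among the 10. The replicate numbers did not pair the samples: deviations of same-numbered KO and WT libraries correlated at -0.071, -0.034 and -0.044 in input and at -0.60, -0.34 and -0.22 in RIP. The block left the RIP count at 0. For the Fmr1 row tested without the filter, it gave an adjusted p of 0.425 (limma) with the log2 difference at 0.75. For ENSMUSG00000087263 the adjusted p rose to 0.102 with the block and to between 0.0606 and 0.229 without KO replicate 2 or any WT replicate, and its log2 change was -5.39 without KO replicate 1. ENSMUSG00000117490 stayed past the threshold in all 10 alternatives given for it. All 10 were edgeR fits, and DESeq2, limma-voom and the surrogate variable were not among them.

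The count of RIP rows, 0, became 1, the Fmr1 row, with no filter on low values and with rows averaged per gene, both overall and above 1.5-fold. Pseudocounts of 0.1 and 10, a mean of at least 4, no centring, quantile normalization, the median of ratios, 1 surrogate variable, robust moderation and each library left out gave 0. DESeq2 and edgeR were not run on the ratios, which are not counts. The mean input change of the RIP set, 0.046, was 0.035 with the 500 rows of highest moderated t, a set that passed (camera with the preset correlation, p = 0.0377). The estimated correlation, which took the main set from p = 0.0837 to p = 0.525, was not run for it. It was 0.012 without KO replicate 2 or WT replicate 1 and 0.070 without KO replicate 3 or WT replicate 3. With RIP and input taken from different replicate numbers, where each number has its own set of 100 genes, the mean was -0.066, -0.020 and -0.064. The correlation of RIP with input likewise became -0.0800, -3.82e-05 and -0.0200. A shared input denominator, simulated for libraries of the same number, gave a positive Pearson correlation of 0.246, above the observed 0.117. Why the simulated value was higher, and why the crossed values lay below 0, was not tested. The length correlation of 0.0905 was 0.00177 for replicate number 3, and the cause was not tested. The windows of 5, 10 and 20 Mb around Fmr1 each held the same 10% of called genes, Fmr1 itself and 0 others. The planned test of these shares is left out, since the gene at the centre decides it. The mitochondrial list passed in none of its alternatives. Gene lists in RIP gave no value, since no list member could be found there. Whether depth limited the calls was not tested on these counts.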

Other observations

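The tests of the distal chromosome ends and of the surrogate variable were chosen after the results were seen. The tests of input shift and of abundance were set after the long-gene pattern was seen, before their own values were. The bootstrap standard error was added to the input shift after its value was seen. The 14 tested Y genes as a set were lower in KO (camera adjusted p = 0.00457), but not with an estimated correlation (adjusted p = 0.372). The median log2 change of the 14 was -0.40. Of the 14, 4 lie at the distal end that shares copies with X, and no test of the set without them is given. The result therefore does not show whether Y itself changed. Y genes outside the distal end had 423 to 648 reads per library, 24.5 ± 2.38 CPM in KO and 25.6 ± 2.29 in WT (SD, n = 3 each). The 2 genes with the most reads held 43.0% of them.

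The distal ends of X and Y share near-identical sequence. For the fewer KO reads at both ends, reads placed on one near-identical copy in place of another would leave the sum over both ends equal. The sum differed by -1.62 on the log2 scale, with every KO library below every WT library, which argues against that exchange; reads lost altogether for want of a placement were not tested. A lower dosage of the whole X chromosome is also argued against, since the median of the other X genes was -0.00857. A distal X that differs between the parents of the KO and WT animals stays open, since counts per gene carry no sequence. Of the 10 tested genes of both ends, 9 had lower estimates in KO. That count is no evidence for it, since the X end was set to start at a called gene and the ends share copies. Loss of binding by FMRP stays open as well, since 0 genes of these ends had a row in the RIP table.

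For the long genes with larger RIP ratios in WT, the difference measured in input was small. Their median input change exceeded that of other genes by 0.0136 (bootstrap SE over genes 0.0031), against a median RIP difference of 0.043. The SE over genes does not measure the spread between libraries, and the medians are on different scales, log2 CPM and log2(value + 1). An input difference between KO and WT is therefore not excluded as the cause. Library differences unrelated to genotype stay open: the ratio of WT-higher to KO-higher long genes was 3.25 with 1 surrogate variable in the fit, but the counts were 133 and 99 without WT replicate 1. Abundance stays open as well, since the excess over other genes was 2.27-fold and 1.93-fold in the upper and middle of 3 equal groups by input level but 0.881-fold in the lowest. Binding of long transcripts by FMRP was not tested separately, and the set did not pass its own test.

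The 10 possible splits of 6 libraries are too few for a share under 0.05. For the input, the real split called 10 genes and the highest other split 47, so that 2 of the 10 splits, the real one among them, reached 10. For RIP, 1272 rows had an unadjusted p under 0.05 in the real split, the 1 split to reach that number, and 1248 in the highest other. For the long genes, the WT-higher less the KO-higher genes were 94 in the real split and 134 in the highest other, so that 2 splits reached 94. The split that gave 47 input genes was also the one that gave 134 and 1248, with 159 RIP rows past the adjusted threshold: KO replicate 1 with WT replicates 2 and 3, against KO replicates 2 and 3 with WT replicate 1. An input count several times the real one may reflect a structure of the samples that the genotype does not follow, which was not tested. The surrogate variable separated the libraries as this split does in RIP. It did not in input, where KO replicate 3 (-0.55) lay with KO replicate 1 (-0.46). In the RIP data the same split had calls where the real split had 0, though the real split had the most rows before adjustment. The assays are not separate evidence for such a structure if the ratios carry the same-numbered input, which the sources do not state.

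Deviations of each RIP library from its group mean correlated negatively with those of the input library of the same number in all 6 cases (-0.17 to -0.075, across genes), while the 30 other combinations ran from -0.096 to 0.135. Such deviations cancel out within a group, so a negative value pushes the other combinations of that group upwards. Part of the contrast is therefore fixed by the centring. Fmr1 lies on the X chromosome, so daughters of a father without a working copy all inherit that allele, and homozygous KO and WT females cannot share a father. The KO allele carries an insertion in an exon of Fmr1, so reads from its other exons can remain without a working copy. Fmr1 RNA at 47.4% of WT therefore does not decide whether every KO pool was homozygous. That stays untested, and the labels do not state it. The design text calls the WT input animals littermates, and the labels give the same strain name for both groups.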
